A study of Mus musculus with 371 samples.

How the data were processed

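Single T cells sorted from B16F10 melanoma tumours of mice were profiled by Smart-seq2, a method that makes full-length cDNA from the RNA of 1 cell. Per the labels' protocols, cells were lysed in plates, RNA was bound to beads, cDNA was amplified for 21 cycles and libraries were made by Nextera XT tagmentation. Each cell's title names a genotype (WT, or KO for Il27ra), a sort (CD8 or CD4), the number 3 beside the genotype, an animal name that differs between the 4 groups, and a last part that is p1 in both CD8 groups and p2 in both CD4 groups. The animal name was read as the plate, which the titles do not say; if the last part names the plate, WT and KO cells of a sort shared it. Under either reading, every group carried 1 name and 1 number, so the 4 groups (WT CD8, KO CD8, WT CD4, KO CD4) are 4 sorted pools of cells with no replicate.

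The values used were gene-level FPKM that the authors deposited, made with Bowtie and RSEM on mm10 and normalized between cells by TMM, per the submitters' processing notes. The versions of these tools are not given there. The table held 23366 genes in 375 columns, of which 371 were single cells and 4 had names with the word Population. Those 4 columns were not used here. Genes are named by symbol in the table. 4 entries with repeated symbols were left out, which left 23362 genes. No 2 cells had identical values, and the highest correlation between 2 cells was 0.687.

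Read counts per cell were not used here, so depth was read from the values themselves. Among 3808 genes with 1 annotated transcript longer than 500 nucleotides, values under 8 FPKM were matched to the step that 1 read would give at each transcript's length. In the median cell of each group, 26.3% to 27.8% of these low values lay within 0.2 (log2) of such a step, against 12.5% to 13.9% with transcript lengths shuffled. The step put the median library near 496054 counted fragments in WT CD8, 496007 in KO CD8, 502931 in WT CD4 and 496007 in KO CD4, after the scaling by TMM. At that depth, 1 read of a transcript of 2 kilobases corresponds to 0.994 to 1.01 FPKM, so detection at 1 FPKM includes values from 1 read.

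Cells with at least 1000 genes at 1 FPKM or above were kept, which left 350 of 371. The value of a gene in a group was the mean over cells of log2(FPKM + 1), and differences are KO minus WT within a sort, or CD4 minus CD8 within a genotype. A gene was measured in a comparison when at least 20% of the cells of either group had it at 1 FPKM or above. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. A share of 0 carries the upper limit that 3 counts allow. Each group is 1 sample, so no test between groups was made: no p-value, standard error or count of changed genes was computed from cells. Spreads are SD over cells and describe the cells of 1 pool.

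The comparisons, the filters, the gene lists and the rule for named genes were fixed before the data were examined. The 17 main lists held co-inhibitory receptors, the receptors Pdcd1, Havcr2, Lag3 and Tigit, regulators linked to IL-27, the IL-27 receptor pathway, interferon-stimulated genes, cytotoxic effectors, naive and memory genes, transcription factors of effector and exhausted cells, co-stimulatory receptors, regulatory T cell genes, helper T cell factors, residency and homing genes, cell cycle, glycolysis, respiratory chain, MHC class I presentation, and survival and death genes. The remaining lists, for 34 in all, covered T cell identity, CD8 and CD4 lineage, immediate early and heat shock genes, ribosomal protein genes, mitochondrially encoded genes, sex-linked genes, and markers of 10 other cell types. 4 members were matched by an older symbol, such as Vsir as 4632428N05Rik. A list with at least 3 measured members was described by its median difference and by the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean expression. Percentiles below 2.5 or above 97.5 are called low or high. They describe these libraries and are not tests of the genotype.

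Named genes were Il27ra, the members of the co-inhibitory and IL-27 regulator lists, the 10 genes with the highest and the 10 with the lowest difference in each sort, the 10 highest and 10 lowest with the same sign in both sorts (by the smaller difference), the same for CD4 against CD8 over both genotypes, and the members of other lists with the largest differences. Receptor gene segments, predicted genes and pseudogenes were left out of the ranked parts. Some genes that this rule selects are not reported here. They stay in the list medians and percentiles but not in the counts of named genes.

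Cells were clustered over 2000 variable genes, 20 principal components and 15 nearest neighbours with the Leiden algorithm at resolution 1, with fixed seeds. Clusters were named from fixed marker lists, where the mean difference of the best list was over 1 and led that of the next list by at least 1. No doublet caller was used. Gene positions were taken from the GENCODE vM21 annotation of mm10. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

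The steps were tested on simulated data, made by splitting the cells of 1 WT group at random and multiplying the values of chosen genes. The inserted differences were returned by the code, which checks only its arithmetic. With the noise of the split, genes multiplied by 0.25 differed by -0.94 where -0.67 was inserted in the CD8 simulation and by -0.81 where -0.74 was inserted in the CD4 simulation, and genes multiplied by 2 differed by 0.02 where 0.38 was inserted and by 0.38 where 0.36 was inserted. A random split of 1 group can thus shift differences by amounts of this size. Relative to genes of like expression, 66% to 88% of single changed genes had the right sign. Of 100 lists of 12 unchanged genes, 6 lay outside the percentiles 2.5 to 97.5 in the CD8 simulation (5487 genes) and 5 in the CD4 simulation (3698 genes). These lists were drawn at random, so that share was set by the design. It gives no error rate for lists whose genes vary together. A list of 12 genes multiplied by 0.25 reached the percentile 5.29 in the CD8 simulation and 0.08 in the CD4 simulation.

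25 pairs of a result and an alternative were planned, and some alternatives served more than 1 result. They changed the pseudocount (0.1 or 10), the order of averaging and logs, and the filter on cells (none, or 2000 genes) and on genes (5% of cells, or none). They also changed the scaling (equal sums per cell, equal medians of detected genes, or cells weighted to equal detected genes, where each quartile of detected genes counted the same in both groups and differences inside a quartile remained). Others kept only cells whose Cd4, Cd8a and Cd8b1 transcripts matched the sort, left out Treg-like cells or cells with markers of other types, changed detection to any value above 0 or to 10 FPKM, or changed the clustering (1000 variable genes, 10 components, resolution 0.5 or 1.5). Leaving out an activated cluster of cells, and leaving out CD4 cells with Foxp3, were added after the data were seen.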

Results

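Transcriptomes of single T cells from B16F10 tumours were described, to look for genes that depend on the IL-27 receptor in T cells inside the tumour. After the filter, 90 of 94 WT CD8 cells, 86 of 90 KO CD8 cells, 85 of 94 WT CD4 cells and 89 of 93 KO CD4 cells remained. The median number of genes at 1 FPKM or above was 2148 in WT CD8, 1955 in KO CD8, 1661 in WT CD4 and 1868 in KO CD4 cells. The mean was 2474 ± 942 (SD over cells) in WT CD8, 2010 ± 417 in KO CD8, 1885 ± 868 in WT CD4 and 2050 ± 759 in KO CD4 cells. The FPKM of a cell summed to a median of 557200, 515626, 475300 and 535351 in the same order. The differences between WT and KO ran in opposite directions in the 2 sorts. Each group was 1 sorted pool with its own name, read as a plate, and no replicate, so pool and genotype cannot be told apart in any comparison.

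The targeted gene, Il27ra (mm10, chromosome 8, 84030294 to 84042589, minus strand), encodes the IL-27 receptor alpha chain. It was at 1 FPKM or above in 51.1% of WT CD8 cells (95% interval 40.3% to 61.8%) and 53.5% of KO CD8 cells (42.4% to 64.3%). In the CD4 sort it was found in 50.6% of WT cells (39.5% to 61.6%) and 50.6% of KO cells (39.8% to 61.3%). Its mean was 51.7 FPKM in WT CD8, 58.4 in KO CD8, 83.1 in WT CD4 and 47.6 in KO CD4 cells. The difference of mean log2 values was 0.25 in CD8 and -0.35 in CD4 cells, with SDs over cells of 3.17 to 3.51. The table gives 1 value per gene over all of its exons and cannot show whether a deleted part of Il27ra was read, so it does not check the genotype labels. The cells are therefore named below as cells labelled KO.

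The sorts mostly matched their lineage transcripts. Cells with Cd8a or Cd8b1 and without Cd4 were 83 of 90 WT and 84 of 86 KO-labelled cells of the CD8 sort, and cells with Cd4 and without Cd8a and Cd8b1 were 54 of 85 WT and 61 of 89 KO-labelled cells of the CD4 sort. Cd4 was found in 0 of 90 and 0 of 86 cells of the CD8 sort, which allows shares of up to 3.33% and 3.49%, and in 87.1% and 87.6% of the WT and KO-labelled cells of the CD4 sort. Cd8a was found in 83.3% and 81.4% of CD8 cells, and in 2.35% and 1.12% of CD4 cells. Cd8b1 was found in 86.7% and 91.9% of CD8 cells at medians of 1068 and 903 FPKM where detected. In CD4 cells, Cd8b1 was detected in 24.7% and 21.3% at medians of 2.13 and 2.95 FPKM, near the level of 1 read. Foxp3, the lineage factor of regulatory T cells, was found in 54.1% of WT CD4 cells (43% to 65%), 39.3% of KO-labelled CD4 cells (29.1% to 50.3%), 4.65% of KO-labelled CD8 cells and none of the WT CD8 cells (up to 3.33%). Xist was found in 60% to 81.1% of cells, and Ddx3y of the Y chromosome in none.

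In CD8 cells labelled KO, interferon-stimulated and antigen presentation genes had lower means than in WT CD8 cells, as did perforin and the receptors Lag3, Havcr2 and Pdcd1. Genes of naive and memory cells were higher relative to other genes. Prf1, which encodes perforin, had the lowest difference of all ranked genes, -3.02. It was found in 46.7% of WT cells (36.1% to 57.5%) at a mean of 429 FPKM over all cells, and in 14% of cells labelled KO (7.42% to 23.1%) at a mean of 42.8 FPKM.

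Of 26 measured interferon-stimulated genes in CD8 cells, 25 had a lower mean in cells labelled KO and 24 lay below the median of all genes. Their median difference was -0.95, at the percentile 0.01 of random lists. Among the largest differences were those of the peptide transporter Tap1 (-2.70; 82.2% against 52.3% of cells), Bst2, which encodes tetherin (-2.34; 44.4% against 17.4%), the immunoproteasome gene Psmb9 (-1.87) and the guanylate-binding protein gene Gbp6 (-1.86). MHC class I presentation genes, which share Tap1, Psmb8 and Psmb9 with that list, had a median of -1.12 (percentile 0.07), with 11 of 12 lower. Tap2 differed by -2.31, Psmb10 by -1.81 and Nlrc5, the transactivator of MHC class I genes, by -1.79, while H2-D1 differed by 0.07.

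The co-inhibitory receptors had a median of -1.01 in CD8 cells (percentile 0.61, kept low in 9 of 13 alternatives), with 8 of 11 measured members lower and 3 higher. Pdcd1, Havcr2, Lag3 and Tigit, which encode PD-1, Tim-3, Lag-3 and TIGIT, had a median of -1.50 (percentile 0.19), from which Tigit stood apart. Lag3 differed by -1.79 (32.2% against 18.6% of cells), Havcr2 by -1.60 (27.8% against 8.14%) and Pdcd1 by -1.41 (40% against 26.7%), while Tigit differed by 0.02 (58.9% against 62.8%). Klrc1, which encodes the inhibitory receptor NKG2A, differed by -1.78, and Ctla4 by 0.14. At least 3 of the 4 receptor transcripts were found together in 27.8% of WT CD8 cells (18.9% to 38.2%) and 8.14% of CD8 cells labelled KO (3.34% to 16.1%). All 4 were found in 20% (12.3% to 29.8%) and 3.49% (0.725% to 9.86%). At least 2 were found in 43.3% (32.9% to 54.2%) and 26.7% (17.8% to 37.4%), intervals that overlap, and at least 1 in 67.8% and 77.9%. The planned cutoffs were at least 2 and at least 3.

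**Figure D1:**
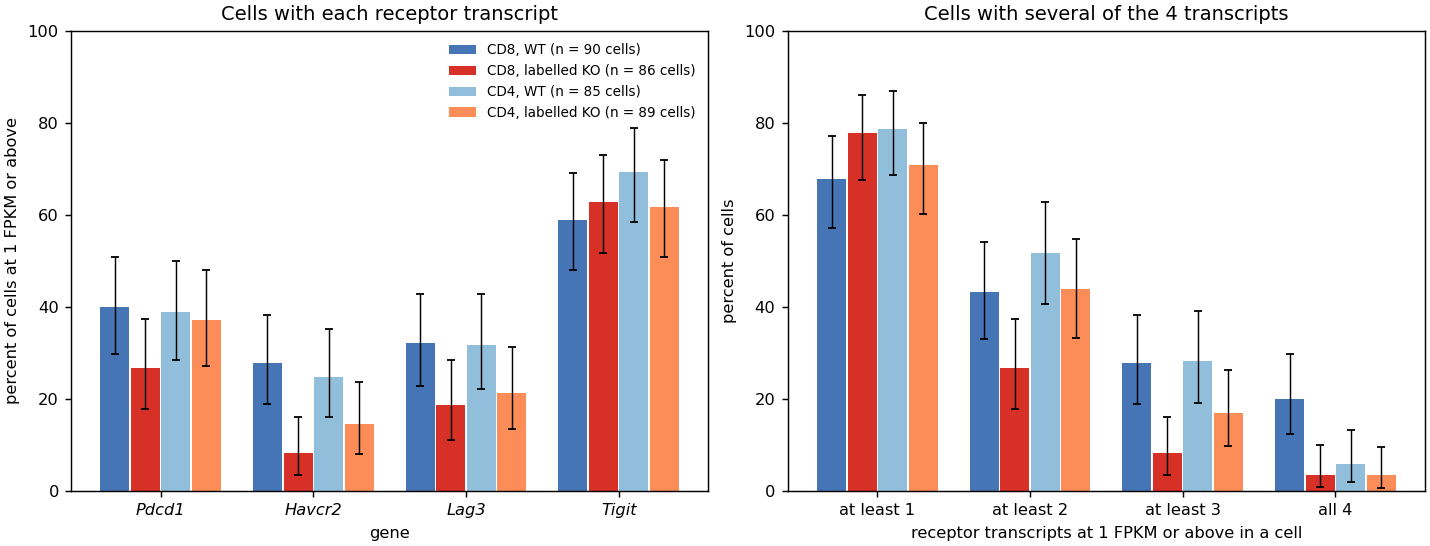
Percent of cells with each of 4 co-inhibitory receptor transcripts at 1 FPKM or above (left) and with at least 1, 2, 3 or all 4 of them (right), in WT and KO-labelled cells of each sort; bars are shares and lines are exact 95% intervals for counting error. In CD8 cells, at least 3 of the 4 were found in 27.8% of WT cells and 8.14% of cells labelled KO.

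Among regulators linked to IL-27, all 10 measured members had a lower mean in CD8 cells labelled KO. Their median of -0.52 lay at the percentile 45.2, and the median of all 4686 measured genes was itself -0.40. With cells weighted to equal numbers of detected genes, the list median was -0.54 (percentile 2.44) and that of all genes -0.16. The list stayed within the range of random lists in 12 of 13 alternatives. Stat3 (-1.52) and Tbx21 (-0.91), which encodes T-bet, were among the largest differences. The receptor pathway list had a median of -0.50 (percentile 45.3), with Tyk2 at -0.74 and Jak1 at 0.09. Prdm1 was found in 13.3% of WT and 6.98% of KO-labelled CD8 cells, Il10 in 1.11% and 1.16%, and Maf in 2.22% and 4.65%. These 3 were too rare for the comparison of means.

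The naive and memory list had a median of 0.15 in CD8 cells (percentile 99.97), with 12 of 13 members above the median of all genes. The IL-7 receptor gene Il7r differed by 1.07 (54.4% against 69.8%), the transcription factor gene Tcf7 by 1.00 (52.2% against 65.1%), Slamf6 by 1.00 and Bcl2 by -0.75. Residency and homing genes had a median of 0.15 (percentile 99.96), with Itgb1 at 0.84 and Ccr2 at 0.68 but Rgs16 at -1.26. Transcription factors of effector and exhausted cells had a median of -0.87 (percentile 2.03, kept below 2.5 in 3 of 13 alternatives), with Tox at -1.15, Id2 at -1.10 and Rbpj at -1.09. Cytotoxic effectors had a median of -0.61 (percentile 15.2). Beside Prf1, Cst7 differed by -1.89, Klrk1 by -1.70, Gzmb by -1.23 (37.8% against 24.4%) and Ifng by -0.88 (23.3% against 10.5%).

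Metabolic genes were lower as well in CD8 cells labelled KO. The glycolysis list had a median of -0.98 (percentile 0.10), with all 13 measured members lower, among them Pgam1 (-2.14) and Pgk1 (-1.92). The respiratory chain list had a median of -0.99 (percentile 0.02, kept low in 10 of 13 alternatives), with 30 of 31 lower, among them Ndufa2 (-1.81) and Cox5b (-1.70). Cell cycle genes had a median of -0.79 (percentile 1.02, kept low in 9 of 13 alternatives), with Tuba1b at -2.44, Pcna at -1.59 and Mcm5 at -1.48. Co-stimulatory receptors had a median of -0.31 (percentile 71.3) and went both ways, with Tnfrsf9 at -1.96, Tnfrsf18 at -1.67, Cd226 at 1.22 and Cd28 at 0.79. Survival and death genes had a median of -0.71 (percentile 11), with Bcl2a1b at -1.25 and Bcl2a1d at -1.22. The 5 measured regulatory T cell genes had a median of -0.07 (percentile 90.9), with Tnfrsf9 and Tnfrsf18 lowest. The 4 helper genes had a median of -0.12 (percentile 88), with Gata3 at 1.03.

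The 10 lowest differences in CD8 cells were those of Prf1, Tap1, Psme1 (-2.46), Tuba1b, Vmp1 (-2.36), Zmat2 (-2.35), Bst2, Dad1 (-2.33), the heat shock gene Hsp90aa1 (-2.32) and Tap2. The 10 highest were those of Gpr18 (1.62), Klhl6 (1.57), Fam65b (1.43), Txnip (1.40), Kbtbd11 (1.38), Abcg1 (1.30), Rnf145 (1.22), Cd226, Cdc25b (1.21) and Ppp1r15a (1.18). Gpr18 was found in 27.8% of WT cells and 46.5% of cells labelled KO. Immediate early and heat shock genes, which tissue dissociation can induce, had a median of -0.04 (percentile 99, kept high in 7 of 13 alternatives), with Btg2 at 1.09 and Hsp90aa1 at the low end. With cells weighted to equal numbers of detected genes, the percentile was 3.76 for the 4 receptors (median -0.67) and 31.2 for glycolysis. Without a cluster of cells called activated (described with the clusters), an alternative chosen after the data were seen, the percentile was 41.6 for co-inhibitory receptors, 62.4 for naive and memory genes, 59.6 for exhaustion factors (median -0.02), 24.4 for glycolysis and 18.1 for the cell cycle, and Lag3 differed by 0.08. There, 8 co-inhibitory receptors passed the filter on genes, against 11 among all CD8 cells. Of Pdcd1, Havcr2, Lag3 and Tigit, 2 passed it. The value of Lag3 was not subject to that filter.

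In CD4 cells labelled KO, interferon-stimulated genes again had lower means than in WT CD4 cells, while S100a10, Cd69 and ribosomal protein genes had higher means. Socs3, a STAT-induced inhibitor of cytokine signalling, had the lowest difference, -3.07. It was found in 63.5% of WT cells (52.4% to 73.7%) at a mean of 287.5 FPKM, and in 29.2% of cells labelled KO (20.1% to 39.8%) at a mean of 75.7 FPKM. S100a10 had the highest difference, 3.30, with 48.2% of WT cells at a mean of 330 FPKM and 79.8% of cells labelled KO at 944 FPKM. The median of all 3864 measured genes was 0.23, and 0.07 with cells weighted to equal detected genes.

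Of 24 measured interferon-stimulated genes in CD4 cells, 19 had a lower mean in cells labelled KO and 22 lay below the median of all genes. The list median was -0.44, below all 10000 random lists. The largest differences were those of Igtp (-2.33; 60% against 37.1% of cells), Iigp1 (-1.79; 28.2% against 7.87%), Gbp4 (-1.65; 48.2% against 28.1%) and Gbp6 (-1.29), which encode interferon-induced GTPases, and Ly6a (-1.18). Psmb8 differed by 0.77 and Ifi27l2a by 0.46. MHC class I genes had a median of -0.12 (percentile 0.11, kept low in 12 of 15 alternatives), with Nlrc5 at -0.83 and Tap1 at -0.30.

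The co-inhibitory receptors had a median of -0.31 in CD4 cells (percentile 0.04, kept low in 13 of 15 alternatives), with 9 of 12 measured members lower. Without cells carrying other cells' markers, which left 35 WT and 42 KO-labelled cells, their median was 0.37 (percentile 15.7). The mean of random lists was then 0.63 and the median of all genes 0.53, so 0.37 was still below both. Lag3 differed by -1.37 (31.8% against 21.3%), Havcr2 by -0.89 (24.7% against 14.6%), Entpd1 by -0.79, Tigit by -0.54 and Pdcd1 by -0.02, while Cd200r1 differed by 0.87 and Vsir by 0.77. Pdcd1, Havcr2, Lag3 and Tigit together had a median of -0.71 (percentile 0.03), and of -1.13 (percentile 0) without cells carrying other cells' markers. At least 2 of the 4 were found in 51.8% of WT CD4 cells (40.7% to 62.7%) and 43.8% of CD4 cells labelled KO (33.3% to 54.7%). At least 3 were found in 28.2% (19% to 39%) and 16.9% (9.75% to 26.3%) of the same groups. The intervals overlap for both cutoffs. Among CD4 cells without Foxp3, at least 3 were found in 1 of 39 WT cells (2.56%, interval 0.0649% to 13.5%). For cells labelled KO, the count was 2 of 54 (3.70%, 0.452% to 12.7%). Leaving out cells with Foxp3 was chosen after the data were seen, and these counts are too small to show a direction. Leaving out Treg-like cells was planned. There, at least 3 were found in 11.5% of WT cells (4.74% to 22.2%) and 4.55% of cells labelled KO (0.947% to 12.7%). The WT share was again higher there, and the intervals again overlap.

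Regulators linked to IL-27 had a median of -0.06 in CD4 cells (percentile 2.27, kept low in 10 of 15 alternatives), with 7 of 13 members lower. Besides Socs3, Stat3 (-0.76) was lower, and Ikzf3 (1.20), which encodes Aiolos, was higher. Il10 was found in 12.9% of WT and 12.4% of KO-labelled cells, Prdm1 in 23.5% and 21.3%, and Maf in 37.6% and 33.7%, each share lying within the 95% interval of the other. The receptor pathway list had a median of -0.14 (percentile 1.73, kept below 2.5 in 7 of 15 alternatives), with Il6st at -0.62 and Jak1 at 0.75.

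Regulatory T cell genes had a median of -0.03 in CD4 cells (percentile 2.04, kept below 2.5 in 6 of 15 alternatives) and went both ways, with Ikzf2 at -1.28, Foxp3 at -1.07, Klrg1 at 1.28 and Ccr8 at 1.22. Naive and memory genes had a median of -0.17 (percentile 0.94, kept low in 12 of 15 alternatives), with Cd27 at -1.48, Ltb at -1.16 and S1pr1 at 0.83. Residency and homing genes had a median of 0.76 (percentile 95), with 14 of 15 higher, among them Cd69 (2.55), Itgb7 (2.39), Rgs1 (2.31) and Cxcr6 (1.62). Respiratory chain genes had a median of 0.61 (percentile 95.8), with Cox4i1 at 1.28 and Cox7c at 1.24. Cell cycle genes had a median of -0.18 (percentile 1.12, kept below 2.5 in 5 of 15 alternatives) but a mean of 0.09, with Mcm6 at 1.23 and Mcm7 at -0.78. The lists of cytotoxic effectors (median 0.15, percentile 24.9), exhaustion factors (0.11, 22.3), co-stimulatory receptors (0.18, 5.75), helper genes (0.01, 19.6), glycolysis (0.35, 23.9) and survival and death genes (0.25, 47.6) lay within the range of random lists. Their largest differences were those of Nkg7 (-1.54), Nr4a1 (2.26), Cd27 (-1.48), Gata3 (1.40), Pgam1 (1.19) and Bcl2a1b (1.81). The glycolysis median turned to -0.28 (percentile 0.33) with cells weighted to equal detected genes. Among cells with at least 2000 genes it was -0.49 (percentile 1.26). Its percentile kept its place in 13 of 15 alternatives.

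The 10 lowest differences in CD4 cells were those of Socs3, the interferon-induced Tgtp2 (-2.35) and Igtp, Serpina3g (-1.92), Iigp1, Gimap3 (-1.69), Gbp4, Nkg7, Cd27 and Gimap4 (-1.48). The 10 highest were those of S100a10, Emb (2.61), Cd69, S100a6 (2.53), Ier2 (2.51), Crip1 (2.5), Itgb7, Rgs1, Nfkbid (2.31) and the T cell receptor adaptor gene Lat (2.28). Ribosomal protein genes were higher for all 26 members, with a median of 1.06 (percentile 99.4, kept high in 10 of 15 alternatives) and Rps2 at 1.69. In CD8 cells their median was -0.34 (percentile 43.9), with Rps9 at -0.75. Immediate early and heat shock genes had a median of 0.52 in CD4 cells (percentile 49.5), with Ier2 and Nfkbia (2.11) highest. Among cells with at least 2000 genes, the percentile was 28.1 for co-inhibitory receptors (median -0.22), 6.22 for the 4 receptors (-0.76), 57.6 for IL-27 regulators (-0.03), 27 for the receptor pathway (-0.33) and 12 for naive and memory genes (-0.38). Without cells that had Foxp3, an alternative chosen after the data were seen, it was 24.5 for MHC class I, 99.1 for regulatory and 12.2 for ribosomal protein genes (median 0.24), and Nkg7 differed by 0.32. The regulatory list then had 7 measured genes, against 15 among all CD4 cells. Its percentile there and that over all CD4 cells thus describe different sets of genes.

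**Figure D2:**
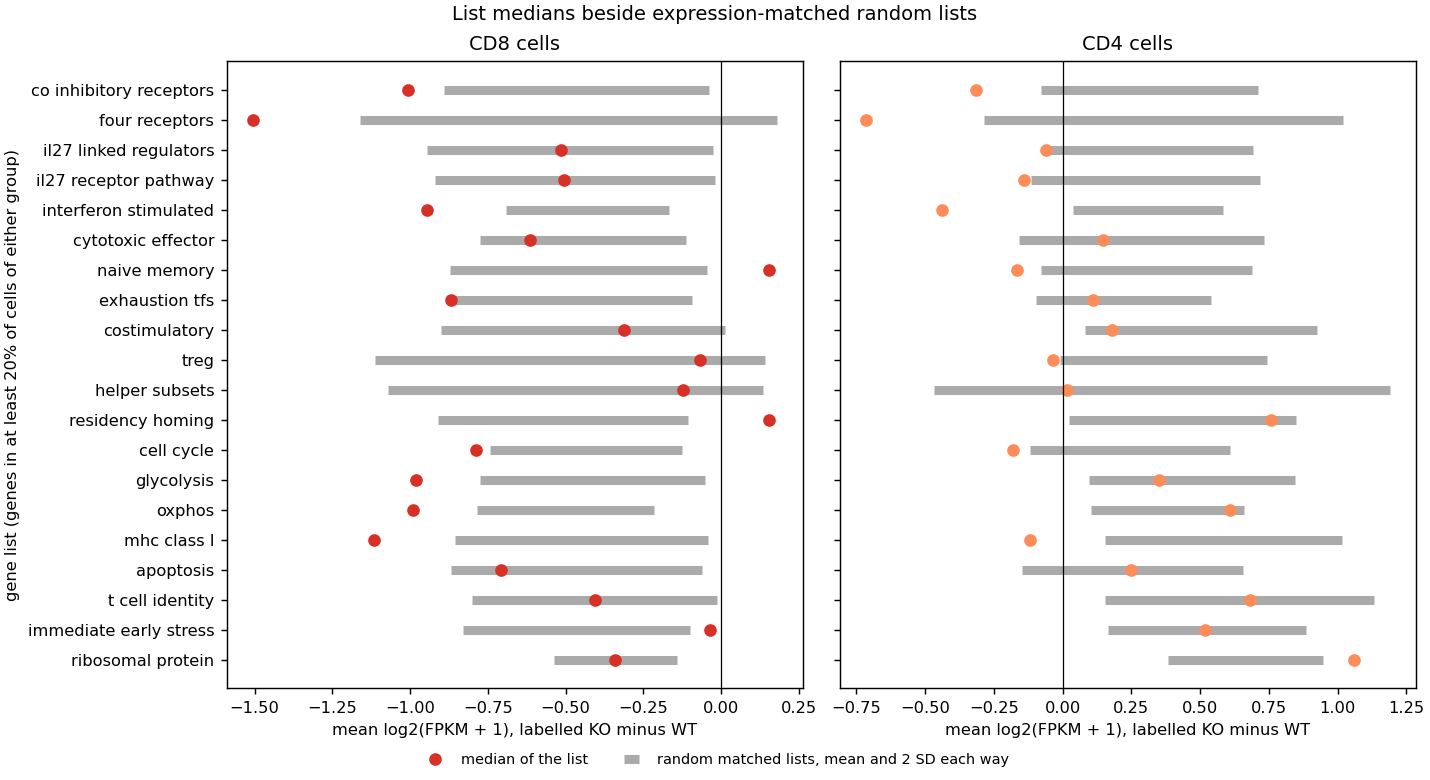
Median difference of mean log2(FPKM + 1), cells labelled KO minus WT, of each gene list with at least 3 measured members in CD8 cells (left) and CD4 cells (right); grey bars are the mean of random expression-matched lists and 2 SD each way. Interferon-stimulated genes lay below the bar in both sorts, at -0.95 and -0.44.

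Across both sorts, the genes with the lowest differences, cells labelled KO minus WT, included interferon-induced genes and Lag3. Tgtp2 differed by -2.15 in CD8 and -2.35 in CD4 cells, Serpina3g by -2.31 and -1.92, Lag3 by -1.79 and -1.37, and Odc1 by -1.32 and -1.38. Gbp6 (-1.86 and -1.29), Ly6a (-1.82 and -1.18), Rtn3 (-1.16 and -1.32) and Gbp4 (-1.11 and -1.65) were also among the 10 lowest. The highest were Clk1 (1.12 and 1.26), Zfp868 (1.10 and 1.39), Btg2 (1.09 and 1.76), Klhl6 (1.57 and 1.07) and Cdc25b (1.21 and 1.05), then Gata3 (1.03 and 1.40), Tmem63a (1.01 and 1.05), S1pr4 (0.94 and 1.22), Rnf7 (0.95 and 0.94) and Zfp36l2 (0.93 and 1.03). Of 23 interferon-stimulated genes measured in both sorts, 20 (87%) lay below the median of all genes in both, against 21.3% of all 3621 genes. Across these 3621 genes, which are not independent replicates, the differences of the 2 sorts had a Pearson correlation of -0.01 and a Spearman correlation of -0.05. Both sorts of a genotype may come from the same mouse or tumour, so the second sort need not be an independent repeat. Of the lower genes named, Lag3 differed by 0.08 in CD8 cells without the activated cluster, where single genes were not filtered by detection. Of the higher genes, Klhl6 differed by -0.19 in CD4 cells without Foxp3.

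**Figure D3:**
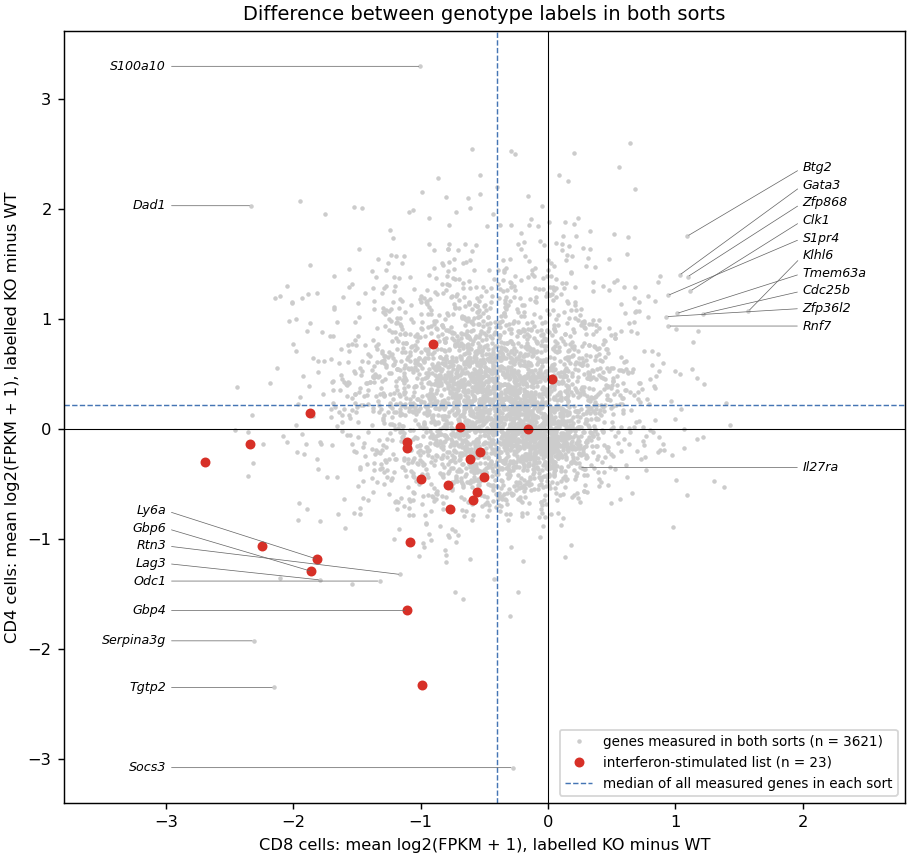
Difference of mean log2(FPKM + 1), cells labelled KO minus WT, in CD8 cells (x axis) and CD4 cells (y axis); each point is a gene measured in both sorts, red points are interferon-stimulated genes, dashed lines are the medians of all measured genes (-0.40 and 0.23), and named genes are among the lowest and highest in 1 or both sorts, with Il27ra. Of 23 interferon-stimulated genes, 20 lay below both medians.

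The comparison of sorts describes which transcripts separate CD4 from CD8 cells in both genotypes. CD8 cells had more of the lineage genes Cd8b1 (CD4 minus CD8, -7.70 in WT and -7.76 in cells labelled KO) and Cd8a (-6.71 and -6.09) and of the cytotoxic genes Nkg7 (-5.16 and -6.03), Ctsw (-6.16 and -5.02), Ccl5 (-5.00 and -4.56) and Klrd1 (-4.16 and -3.41). Ly6c2 (-6.05 and -4.35), Ms4a4b (-4.98 and -3.10) and Epsti1 (-2.38 and -3.19) were lower in CD4 cells as well. CD4 cells had more Cd4 (6.57 and 6.67), Tnfrsf4, which encodes OX40 (4.30 and 4.82), Foxp3 (4.61 and 3.18), Icos (2.75 and 3.74), Ctla4 (2.98 and 2.38), Tnfrsf18 (2.34 and 4.21), Cd5 (2.65 and 2.90), Hif1a (2.45 and 3.15), Ass1 (2.45 and 2.97) and Crem (2.21 and 2.49). The median over all genes was -0.53 in WT (4729 genes) and 0.03 in cells labelled KO (3956 genes), and the differences of both genotypes had a Pearson correlation of 0.46 and a Spearman correlation of 0.23 across 3756 genes.

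Clustering gave 6 groups of cells. The cluster named Treg-like, with Foxp3, Tnfrsf9, Tnfrsf4, Ctla4 and Tnfrsf18 among its top genes, held 28.2% of WT CD4 cells (19% to 39%) and 25.8% of CD4 cells labelled KO (17.1% to 36.2%). It held 0 of 90 WT CD8 cells and 2 of 86 CD8 cells labelled KO. A cytotoxic CD8-like cluster, with Ccl5, Cd8b1 and Nkg7, held 34.4% of WT CD8 cells (24.7% to 45.2%) and 41.9% of CD8 cells labelled KO (31.3% to 53%). A naive or memory-like cluster, with Ccr7, Tcf7 and Lef1, held 25.6% (16.9% to 35.8%) and 30.2% (20.8% to 41.1%) of the same groups. The other 3 clusters got no name under the rule, since no marker list stood apart enough. The CD4 sort differed most in 2 of them. 1, with Egr1, Nfkbid, Rora, Rgs1 and Btg2 as top genes, held 20% of WT CD4 cells (12.1% to 30.1%) and 40.4% of CD4 cells labelled KO (30.2% to 51.4%). Another, with a median of 1335 genes per cell and Cd4 as its top gene, held 30.6% (21% to 41.5%) and 16.9% (9.75% to 26.3%). The last, with a median of 3430 genes per cell, had Pgk1, Cst7 and Lag3 among its top genes and raised all 10 markers of exhausted CD8-like cells (mean difference 3.61) and 9 of those of cytotoxic CD8-like cells (3.43). It had 45 cells and held 28.9% of WT CD8 cells, 9.3% of CD8 cells labelled KO, 7.06% of WT CD4 cells and 5.62% of CD4 cells labelled KO. Because it was defined partly by the listed genes, clusters were remade without any gene of the main lists, and the remade cluster that shared most cells with it (40) was called activated. That cluster was larger, with 92 cells, and 37 of them came from the Treg-like cluster; of its 35 CD8 cells, 30 came from the cluster of 45 cells, and of its 57 CD4 cells, 10 did. It raised all 10 Treg-like markers (3.25) and 7 of the exhausted CD8-like ones (2.38). It held 27.8% of WT CD8 cells (18.9% to 38.2%) and 11.6% of CD8 cells labelled KO (5.72% to 20.3%). In the CD4 sort it held 29.4% (20% to 40.3%) and 36% (26.1% to 46.8%). At resolution 0.5, which gave 3 clusters, the Treg-like cluster held 57.6% and 39.3% of WT and KO-labelled CD4 cells.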

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

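Leaving out the activated cluster or the cells with Foxp3, and counting the names read as plates per group, were tests chosen after the results were seen. The test of the 4 receptors without the activated cluster was altered after its first run. The other tests were planned.

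Some results had opposite signs in the 2 sorts, and the difference between the sorts was not tested for any of them. The naive and memory list had a median difference of 0.15 in CD8 (percentile 99.97) and -0.17 in CD4 cells (percentile 0.94), KO minus WT, but the CD8 median was -0.02 (percentile 62.4) without the activated cluster, and in CD4 cells with at least 2000 genes the percentile was 12 (median -0.38). The respiratory chain list had a median of -0.99 in CD8 and 0.61 in CD4 cells, where it was -0.05 among cells with at least 2000 genes (percentile 45.4) and 0.10 with mean FPKM first (26.4). S100a10 differed by -1.002 in CD8 and 3.30 in CD4 cells. Cd69, an early activation and residency gene, differed by -0.60 and 2.55, and Lat, a T cell receptor adaptor, by -0.87 and 2.28. Nfkbid differed by -0.54 in CD8 and 2.31 in CD4 cells, and Dad1 by -2.33 and 2.03. Gpr18 differed by 1.62 in CD8 and -0.56 in CD4 cells, and Kbtbd11 by 1.38 and -0.52. The medians of all genes also had opposite signs, -0.40 in CD8 and 0.23 in CD4 cells.

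Interferon-stimulated genes were lower in cells labelled KO in both sorts. In CD8 cells, the list stayed at the percentile 0 with cells weighted to equal detected genes and at 0 without the activated cluster. The value without the cluster argues against fewer cells of that cluster among cells labelled KO as the whole cause. The weighting evened out quartiles of detected genes only, and single cells reached 5520 genes in WT CD8 and 3303 in KO-labelled CD8 cells. It argues against fewer detected genes as the whole cause only between quartiles, not within them. In CD4 cells, it stayed at the percentile 0.1 without cells that had Foxp3, which argues against fewer cells with detected Foxp3 as the whole cause. Regulatory cells in which Foxp3 was missed stay in, so the value does not cover all regulatory cells. The weighting (percentile 0) decides nothing in CD4 cells, since those labelled KO had more detected genes (median 1868 against 1661) and it could not have ended the pattern. If the animal name is the plate, plate of origin and genotype cannot be told apart. If the last part of the title is the plate, WT and KO cells of a sort shared it. With 1 pool per group, mouse or tumour of origin and genotype cannot be told apart under either reading. Loss of IL-27 signalling stays open as an untested biological explanation.

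Pdcd1, Havcr2, Lag3 and Tigit had a lower median in CD8 cells labelled KO (-1.50, percentile 0.19; random mean -0.49). With cells weighted to equal detected genes, the percentile was 3.76, the median -0.67 and the random mean -0.17, so the list stayed below its random lists by less and missed the low percentile, and fewer detected genes may be part of the cause; among cells with at least 2000 genes the percentile was 0.02. Without the activated cluster, only 2 of the 4 genes passed the measurement filter, so the list was too near the floor to decide (percentile 82.6 for the genes measured among all cells), and fewer cells of that cluster among cells labelled KO stay open as an explanation. The IL-27 receptor, the mouse or tumour of origin and the plate, if the animal name is its name, stay open as well, untested.

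Ribosomal protein genes were higher in CD4 cells labelled KO (median 1.06, percentile 99.4). The percentile was 99.28 with cells weighted to equal detected genes. That argues against fewer detected genes per WT cell as the whole cause only between quartiles of detected genes. Among cells with at least 2000 genes the percentile was 64.1 and the median 0.17. With mean FPKM first the percentile was 92.5 (median 0.34), and without cells carrying other cells' markers 94.8 (median 1.29). Without cells that had Foxp3, the median was 0.24 and the percentile 12.2. Leaving these cells out also removes any difference inside them. A smaller share of regulatory cells among cells labelled KO thus cannot be told from a difference inside those cells. Without the Treg-like cluster the percentile was 97.4 and the median 0.97, so the result depends on how regulatory cells are defined. Loss of the IL-27 receptor stays open, untested, as does the mouse or tumour of origin.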

How the results depend on the processing

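Leaving out the activated cluster and leaving out CD4 cells with Foxp3 were tests added after the data were seen; the others were planned. No paired analysis was possible because the groups compared are 1 pool of cells each and the results come from no test. Cells of cycling clusters could not be left out, since no cluster was named cycling. The list of Pdcd1, Havcr2, Lag3 and Tigit gave no value under the filter on genes without Treg-like cells, without Foxp3 cells or without the activated cluster, since fewer than 3 of them passed it. Depth limits the rare transcripts most, since 1 FPKM is near 1 read.

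Interferon-stimulated genes kept their direction and a percentile under 2.5 in all 13 alternatives in CD8 cells (0 to 0.38) and in all 15 in CD4 cells (0 to 0.1), and MHC class I genes did so in all 13 in CD8 cells (0 to 2.31). Of the list percentiles over all alternatives, 460 kept their place (low, high or within the range of random lists), 75 crossed into that range, 14 left it and 4 went past the middle of the random lists, which need not change the sign of the median. Of values of named genes, leaving aside the 2 filters on genes, which cannot change them, 573 moved by less than 0.5, 4 reversed and the others moved by more; of shares of cells, 47 stayed within their interval and 17 did not. The cause was not tested for any value below.

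With a pseudocount of 0.1, the percentile was 4.87 for exhaustion factors in CD8, and in CD4 3.90 for IL-27 regulators, 5.65 for the receptor pathway, 6.72 for regulatory genes and 98.7 for respiratory chain. With a pseudocount of 10, cell cycle in CD4 was at 6.88. With mean FPKM first, exhaustion factors (3.74) and respiratory chain (3.24) in CD8 and IL-27 regulators (7.33), regulatory genes (13.5) and cell cycle (40.5) in CD4 were affected. With no filter on cells, the values were 4.53 for exhaustion factors and 3.25 for cell cycle in CD8, and 3.64 for the receptor pathway, 6.56 for regulatory genes and 3.92 for cell cycle in CD4.

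Among cells with at least 2000 genes (59 WT and 38 KO-labelled CD8 cells, 25 and 37 CD4 cells), CD8 percentiles were 2.62 for co-inhibitory receptors and 13.9 for exhaustion factors. In CD4 they were 28.1 for co-inhibitory receptors, 6.22 for the 4 receptors, 57.6 for IL-27 regulators (past the middle, median -0.03), 27 for the receptor pathway, 12 for naive and memory, 15.7 for regulatory, 99.8 for residency, 13.6 for cell cycle, 1.26 for glycolysis and 4.83 for MHC class I genes. There, at least 2 and at least 3 of the 4 receptors were found in 57.6% and 39% of WT CD8, 70.3% and 35.1% of KO-labelled CD4, and 76% and 56% of WT CD4 cells. The shares of KO-labelled CD8 cells stayed within their intervals over all kept cells (17.8% to 37.4% and 3.34% to 16.1%).

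With cells whose transcripts match the sort, regulatory genes in CD4 were at 3.03. With sums rescaled, exhaustion factors (2.98) and cell cycle (6.16) in CD8 and the receptor pathway (4.98) and regulatory genes (4.93) in CD4 crossed. With equal medians, IL-27 regulators (3.66), the receptor pathway (3.62) and regulatory genes (5.64) in CD4 crossed. Weighted to equal detected genes, the CD8 values were 3.76 for the 4 receptors, 2.44 for IL-27 regulators, 16 for exhaustion factors and 31.2 for glycolysis, and the CD4 values 4.82 for cell cycle and 0.33 for glycolysis. The scalings moved the median of all genes to between -0.33 and -0.16 in CD8 and between 0.07 and 0.16 in CD4.

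Without Treg-like cells, the receptor pathway in CD4 was at 6.39, and at least 2 and at least 3 receptors were found in 27.3% and 4.55% of KO-labelled and 37.7% and 11.5% of WT CD4 cells. Without cells carrying other cells' markers, which left 33, 34, 35 and 42 cells (at least 2 markers at 1 FPKM, a level at which neutrophil markers alone were found in 38.2% to 45.3% of the cells of a group), CD8 percentiles were 95.9 for naive and memory, 35.8 for exhaustion factors, 15 for cell cycle and 9.69 for respiratory chain. In CD4 they were 15.7 for co-inhibitory receptors, 13.7 for IL-27 regulators, 3.10 for the receptor pathway, 1.03 for cytotoxic, 33 for regulatory and 32.4 for cell cycle genes, and Gimap4 (0.49) reversed.

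With genes in 5% of cells, CD8 percentiles were 7.71 for co-inhibitory receptors, 11.9 for exhaustion factors and 98.3 for helper genes, and CD4 percentiles 2.95 for naive and memory, 24.1 for cell cycle and 98.2 for respiratory chain. With no filter on genes, these were 8.50, 5.47 and 99.4 in CD8 and 4.53, 29.96 and 98.5 in CD4.

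Without the activated cluster, CD8 percentiles were 41.6 for co-inhibitory receptors (8 measured genes, against 11 among all CD8 cells), 62.4 for naive and memory, 59.6 for exhaustion factors (past the middle, median -0.02), 99.9 for regulatory (3 measured genes, against 5), 97 for residency, 18.1 for cell cycle, 24.4 for glycolysis and 3.39 for respiratory chain. Lag3 reversed (0.078), with no filter by detection. In CD4 they were 2.95 for the receptor pathway, 26.1 for cell cycle, 98.9 for respiratory chain and 5.52 for MHC class I.

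Without Foxp3 cells, CD4 percentiles were 98.4 for co-stimulatory, 99.1 for regulatory (past the middle, median 1.16, with 7 measured genes against 15 among all CD4 cells), 2.61 for cell cycle, 24.5 for MHC class I and 12.2 for ribosomal genes (past the middle, median 0.24), and Klhl6 (-0.19) and Nkg7 (0.32) reversed. There, at least 2 and at least 3 receptors were found in 22.2% and 3.70% of KO-labelled and 25.6% and 2.56% of WT CD4 cells. At clustering resolution 0.5, the Treg-like share was 57.6% of WT and 39.3% of KO-labelled CD4 cells, and with 1000 variable genes 41.2% of WT CD4 cells.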

Other observations

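The test on genes beside Il27ra was written down before its result was seen.

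T cell identity genes had a median difference of -0.41 in CD8 cells (percentile 44.4) and 0.68 in CD4 cells (percentile 60.2), KO minus WT. Cd3g differed by -1.10 in CD8 cells, while Lat (2.28) and Zap70 (2.20) were higher in CD4 cells labelled KO. In the CD8 lineage list, Cd8a differed by -0.73 and Cd8b1 by 0.08 in CD8 cells, and in the CD4 lineage list, Cd4 differed by 0.13 and Zbtb7b by -0.02 in CD4 cells. Among sex-linked genes, Xist differed by -0.50 in CD8 and 0.16 in CD4 cells. None of the 14 mitochondrially encoded genes was in the table, nor were the T cell receptor constant genes Trac, Trbc1 and Trbc2, so that measure of cell quality was not used.

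For any 1 other cell type, cells with at least 2 of its markers at 10 FPKM or above made up at most 9.41% of a group. All counts of such cells below need 2 markers. At least 2 melanoma markers at 10 FPKM or above were found in 8.89% of WT CD8 cells (3.92% to 16.8%), 8.14% of KO-labelled CD8 cells (3.34% to 16.1%), 4.71% of WT CD4 cells and 4.49% of KO-labelled CD4 cells. At the same level, macrophage or monocyte markers were found in 5.56%, 1.16%, 5.88% and 5.62% of the 4 groups in that order, dendritic cell markers in 3.33%, 1.16%, 9.41% and 6.74%, and natural killer cell markers in 5.56%, 4.65%, 2.35% and 4.49%. B cell markers were found in 2 cells of WT CD8 and 1 of KO-labelled CD4, neutrophil markers in 1 cell of each WT group, fibroblast markers in 1 KO-labelled CD4 cell, endothelial markers in 1 WT CD4 cell and gamma-delta T cell markers, of which 3 of 8 listed were used, in 0 cells. Erythroid genes were found in 1 KO-labelled CD4 cell, which set the mean of Hba-a1 in that group to 6831 FPKM. Low values of a few marker genes were spread over nearly all cells. Tyr, a melanocyte gene, was at 1 FPKM or above in 95.3% to 100% of cells at means of 5.80 to 7.70 FPKM, and Cxcr2 in 85.9% to 91.1% at means of 4.80 to 6.73 FPKM.

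A hypothesis was that genes beside Il27ra differ in the same way in both sorts, as DNA of another strain carried along with the targeted allele could cause. Among 29 genes within 10 megabases of Il27ra, 34.5% differed with the same sign in both sorts relative to genes of like expression, against 48% of 3435 genes. The mean product of both sorts' differences lay at the percentile 8.67 of random gene sets of the same size. The prediction was a place among the highest sets, so the hypothesis was not borne out for these genes as a set. A mean over all 29 genes cannot tell whether a few of them differ for that cause.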
